A study of Mus musculus with 7 samples.

How the data were processed

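The data are RNA sequencing of the electroporated cortex of 7 C57BL/6J mouse embryos. Per the labels' protocols, Breasi-CRISPR electroporation took place at E13.5 and tissue of the transfected regions was taken at E15.5. RNA was extracted with a Qiagen RNeasy kit and polyadenylated RNA was enriched. The labels give each brain its treatment and its litter. The treatment is Ccnd2 Thr280Ala in 3 brains and the silent control in 4, and each of the 3 litters holds 1 edited brain, with 2 controls in litter 1 and 1 control in each of the other litters. The brains are separate embryos, so that the deposited p-values of single genes cover the spread between embryos within a litter. What change the silent control makes is not given in the sources used here.

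The submitters' processing notes name the genome build mm10 and the tools cutadapt, featureCounts and DESeq2, without versions or settings. The aligner, the gene annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes may share reads. All values used come from the authors' deposited table of 1 DESeq2 comparison, which has no values per library. The mean normalized count of each gene is a signal that the authors deposited, the mean over 7 libraries of read counts divided by size factors. The log2 fold changes and their standard errors are the authors' own, per the file headers. The Wald statistic is a score in the authors' deposited table, equal to the log2 fold change divided by its standard error to within 1.23e-07. The p-value and adjusted p-value of each gene are the authors' deposited values from the DESeq2 Wald test. Recomputed Benjamini-Hochberg values over the 14638 genes with an adjusted p differed from the deposited ones by at most 4.01e-05. Of 25239 genes, 6263 had no count, 18976 had a p-value, and the adjusted p was given from a mean of 7.08 normalized counts upward. Normalization to size factors holds the typical gene at no change, and the median log2 fold change of tested genes was -0.01. Rn45s, a ribosomal RNA gene, took 2.12% of the summed mean normalized counts, and the table held 0 mitochondrially encoded genes.

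The table holds the fold change with both signs and names no direction. It was settled from 694 genes that had a single read in 1 library. They fell into 7 classes of equal values, 3 above 0 and 4 below 0. A negative binomial model with litter and treatment rebuilt the fold change and standard error of every class to within 2.9e-05, with positive values higher in edited brains. A model with treatment only was off by up to 0.19, and with the opposite sign 0 assignments of the classes were possible. The same classes gave the size factors, and multiplied by the mean total of 25100000 normalized counts they gave estimated depths of 19400000 to 32800000 reads per library. The libraries of litters 2 and 3 form an edited and a control library in each of 2 pairs, called pair A and pair B, and which litter is which is not known. For 748 genes with a standard error above 2, the same model searched for reads in 1 library only, at a minimum of 10 reads. Tested on simulated data, 160 of 160 such genes for which the model gave a fit were placed in the right library, and 0 of 400 genes with reads in several libraries were placed in 1. Simulated genes for which the model gave no fit were left out of the 160, so the search can miss genes.

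The design fixed before the data were examined planned a model of the counts if counts were given. For a table of only the authors' comparison it foresaw a description with no refit, so no gene-level model was run. Calls use the deposited adjusted p below 0.05. The 34 gene lists and the rule for named genes were also fixed then. The rule takes Ccnd2, and among called genes outside the sex-linked list with a mean of at least 10 normalized counts the 12 largest rises and the 12 largest falls, and up to 4 members of each described list with the smallest p, plus any called member. Its clause that a gene differ the same way in all 3 litters could not be applied without values per library. It gave 21 genes besides Ccnd2, of which 1 is not reported here. Rorb, Npy and Rtl8c are called genes outside the 12 largest falls, Rorb and Npy named as list members and Rtl8c because it lies on chromosome X, a choice made after its value was seen.

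The lists were cell cycle groups (the cyclin D, CDK and RB machinery, G1/S and DNA replication, G2/M), cortical cell types (apical radial glia, intermediate progenitors, deep-layer and upper-layer neurons, neuronal maturation), other cells the tissue could hold (GABAergic interneurons, ganglionic eminence and striatum, Cajal-Retzius cells, diencephalon, oligodendrocyte precursors, endothelium, pericytes, microglia and macrophages, erythroid cells, meninges and fibroblasts, choroid plexus and cortical hem), rostral and caudal patterning genes, and signalling and stress groups (Wnt, Notch, PI3K-AKT-mTOR, p53, apoptosis, interferon, immediate early, hypoxia and glycolysis, integrated stress and unfolded protein responses, cholesterol synthesis, ribosomal proteins). The mitochondrially encoded list had 0 members in the table and sex-linked genes were read as levels only. Lists with at least 5 tested genes, 31 in all, were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistics, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 31. The planned test, camera on expression values, needs values per library, as do an estimated correlation and the fry test, and these were replaced or left out. The list p-values thus compare genes with other genes and do not measure how a list varies between embryos. The same holds for the matched random lists named below. Counts adjusted over the list alone are Benjamini-Hochberg values of the deposited p within a list. In 50 simulated draws with 3 shifted lists each, 89.3% of shifted lists were found and 0.4% of other lists were called. The statistics were drawn independently for each gene, so these rates do not hold for lists whose members vary together. For gene calls, Wald statistics were simulated 20 times over 14638 genes with the deposited standard errors, also independently for each gene.

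Alternatives were other filters on low counts (none, and a mean of at least 100 normalized counts), leaving out sex-linked genes, an adjusted p below 0.1, preset correlations of 0.05, 0.1 and 0.3, ranks of the Wald statistics, and 10000 random lists matched on mean normalized count. The last 6 of these were chosen after seeing the data. Coordinates are from the RefSeq annotation of GRCm38.p6, in which 25041 of 25239 symbols were found, and the Ccnd2 codon from GENCODE M21 on the same assembly. Confidence intervals of 95% are normal intervals from the deposited standard errors. Bootstrap intervals of medians resample genes as if they were independent and do not cover the spread between embryos. Other work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.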

Results

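Polyadenylated RNA was sequenced from the electroporated cortex of 7 mouse embryos of the C57BL/6J strain at E15.5, that is 2 days after in utero electroporation at E13.5. In 3 brains, 1 in each of 3 litters, Breasi-CRISPR had been used to change codon 280 of Ccnd2 from threonine to alanine (Thr280Ala). In 4 brains, 2 in litter 1 and 1 in each of the other litters, a silent CRISPR control had been used. Breasi-CRISPR delivers Cas9, a guide RNA and a DNA donor into the ventricular cells of the embryonic brain by electroporation, so that only part of the cells in a sample carry the edit. The values come from the authors' deposited table of 1 comparison, edited against control, which lists a mean normalized count, a log2 fold change with its standard error (SE), a Wald statistic and p-values for 25239 genes. Genes with a single read placed the library totals at about 20800000, 29800000 and 32800000 reads for the edited brains. The controls had about 19400000, 22300000, 24500000 and 29000000 reads. Of the 25239 genes, 6263 had no count in any library and 14638, all with a mean of at least 7.08 normalized counts, had an adjusted p-value. In the text that follows, positive log2 fold changes are higher in the edited brains.

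The comparison asked how cortical gene expression differed 2 days after the Ccnd2 edit. Ccnd2 encodes cyclin D2, a D-type cyclin that activates CDK4 and CDK6 in G1, and threonine 280 lies in the C-terminal part of the protein through which its degradation is controlled. CCND2 variants at this site have been described in people with megalencephaly-polymicrogyria-polydactyly-hydrocephalus syndrome. In the reference transcript, codon 280 is ACC. It lies on the minus strand of chromosome 6, positions 127130365 to 127130367 of GRCm38 (mm10), in the coding part of exon 5 of 5. The coding sequence around it, codons 273 to 288 of a protein of 289 residues, reads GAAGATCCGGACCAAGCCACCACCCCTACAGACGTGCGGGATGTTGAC and encodes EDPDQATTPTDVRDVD. The gene itself spans chromosome 6, 127125162 to 127152188. Ccnd2 transcript was abundant, with a mean of 27810 normalized counts, and its log2 fold change in the authors' deposited table was 0.08 (SE 0.25, 95% interval -0.42 to 0.58, adjusted p = 0.999). Its total level therefore did not pass the test. The SE of Ccnd2 was 3.65 times the median SE of the 165 genes within 2-fold of its abundance, and none of these 165 genes had a higher one. The table gives no value per brain and no count of edited transcripts, so neither the level in each brain nor the edited share was measured here.

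**Figure D1:**
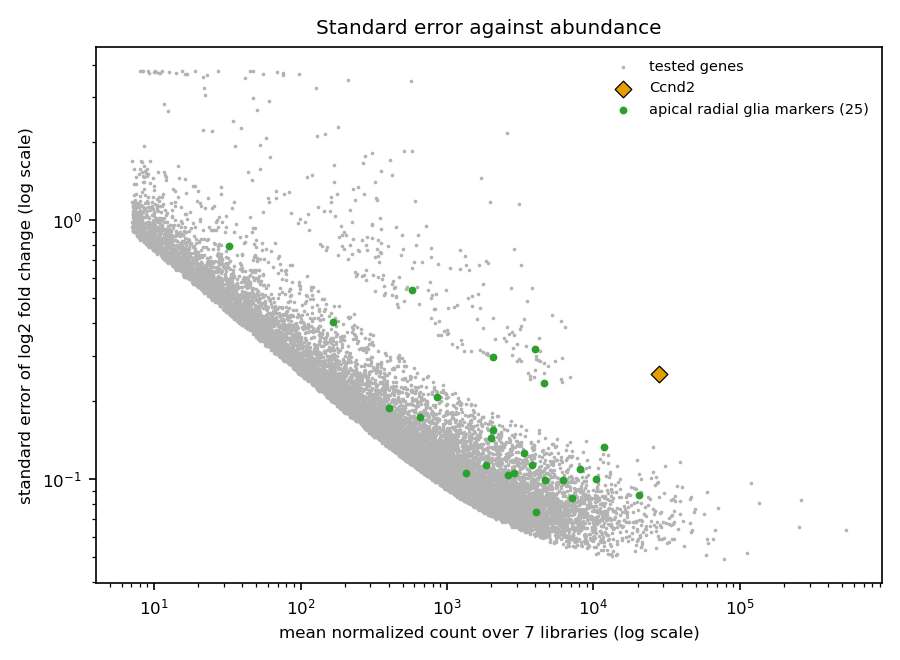
Standard error of the log2 fold change (y axis, log scale) against the mean normalized count over 7 libraries (x axis, log scale) for the 14638 tested genes (grey). Ccnd2 (diamond) has an SE of 0.25 at a mean of 27810 normalized counts, and the 25 apical radial glia markers are shown in green.

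At an adjusted p below 0.05, 36 of 14638 genes differed, 9 higher and 27 lower in the edited brains. Those that fell included receptor, ion transport and synapse genes of neurons, and those that rose included the transcription factor genes Lhx2, Nfix and Tcf4. The smallest p in the authors' deposited table was that of Grin3a, a subunit of NMDA-type glutamate receptors (chromosome 4, 49661611 to 49846023), with a log2 fold change of -1.41 (SE 0.19, adjusted p = 2.2e-09). Gng4, a G protein gamma subunit (chromosome 13, 13784059 to 13827895), fell by 1.19 (SE 0.21, adjusted p = 5.4e-05) in the authors' deposited table. Rorb, a nuclear receptor of layer 4 neurons (chromosome 19, 18930609 to 19111196), fell by 0.58 (SE 0.11, adjusted p = 0.00041) in the same deposited table. Slc12a5, which encodes the potassium-chloride cotransporter KCC2 of neurons, fell by 0.86 (SE 0.17) in the authors' deposited table. Cbln2, a secreted organizer of synapses, fell by 1.21 (SE 0.24) there. Further falls in the authors' deposited table were Unc13c at -1.55 (SE 0.35), Slc24a3 at -1.46 (SE 0.32) and Arl4a at -0.90 (SE 0.21). That deposited table also had Ajap1 at -0.88 (SE 0.23), Scg2 at -0.84 (SE 0.21), Cdh12 at -0.82 (SE 0.16) and Sulf2 at -0.79 (SE 0.16). The largest fold in the authors' deposited table belonged to Rtl3, a retrotransposon-derived gene on chromosome X (106837082 to 106840539), at -6.05 (SE 1.35), but with a mean of only 18.5 normalized counts. Of the 36 genes, 6 differed by at least 1 on the log2 scale, and the smallest size was 0.26.

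The 9 genes that rose did so by less than 1.5-fold each. Lhx2, a transcription factor of cortical progenitors (chromosome 2, 38339271 to 38369737), rose by 0.49 (SE 0.11, adjusted p = 0.0078) in the authors' deposited table. Nedd9, an adaptor protein of focal adhesions (chromosome 13, 41309916 to 41487362), rose by 0.47 (SE 0.10, adjusted p = 0.0045) in the authors' deposited table. Nfix, a nuclear factor I transcription factor (chromosome 8, 84704712 to 84801238), rose by 0.44 (SE 0.10, adjusted p = 0.0072) there. Others in the authors' deposited table were Mid1 at 0.41 (SE 0.09) and the transcription factor Tcf4 at 0.34 (SE 0.09). Smaller rises in that deposited table were those of Igsf8 at 0.34 (SE 0.08), Dck, a kinase of deoxynucleoside salvage, at 0.32 (SE 0.08) and Hs2st1 at 0.26 (SE 0.07). Chromosome X held 4 of the 36 called genes and 524 of the 14638 tested genes (Fisher's exact test, two-sided, p = 0.0387). The test counted genes with no known place as outside chromosome X, and 14579 genes had a known place. It was not part of the design fixed before the data were examined. The sex of the embryos was not separated from the count on chromosome X, and the levels of sex-linked genes are given below. The 4 called genes included Mid1 among the rises and Rtl3 and Rtl8c among the falls, and Rtl8c has close paralogs that could share its reads. Adjusted over all genes with any count, 31 of the 36 calls were kept. Tcf4, Hs2st1, Ajap1 and Scg2 were among those lost, at adjusted p = 0.062, 0.057, 0.051 and 0.050.

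**Figure D2:**
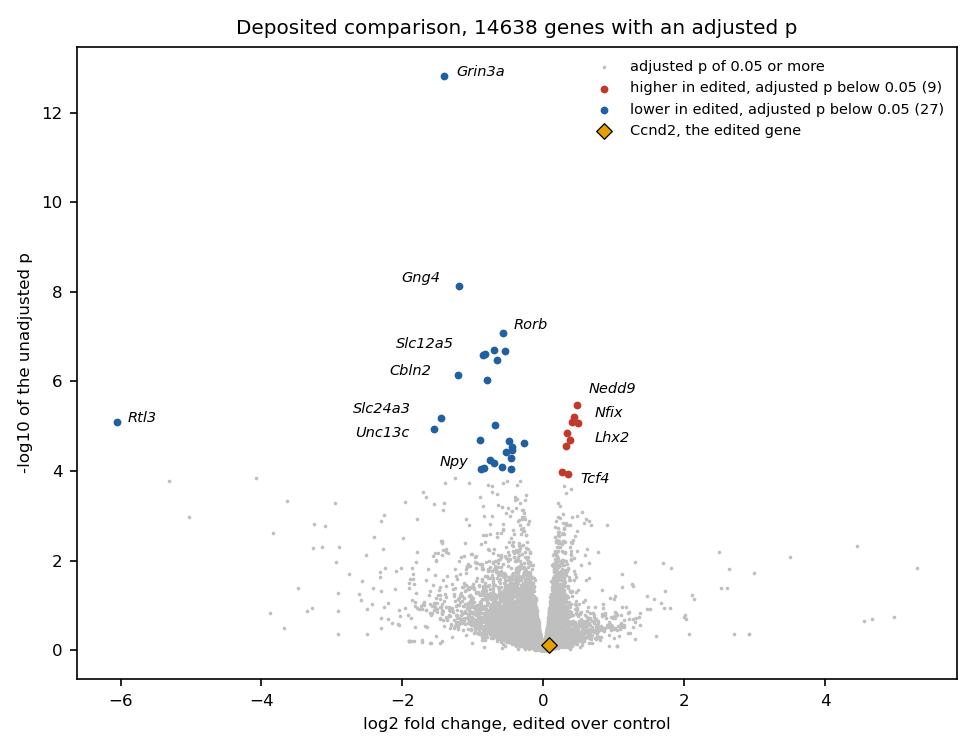
Log2 fold change, edited over control (x axis), against -log10 of the unadjusted p (y axis) for 14638 genes of the authors' deposited table. The 9 genes called higher are red, the 27 called lower are blue, and Ccnd2 (diamond) lies at 0.08.

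Progenitor and cell cycle genes were higher as groups in the edited brains, each by a small amount. Of 35 genes of G1/S and DNA replication, 34 had a log2 fold change above 0, with a median of 0.20. All 30 genes of G2 and mitosis were above 0, with a median of 0.19. All 17 markers of intermediate progenitors, the dividing cells that come from radial glia, were above 0, with a median of 0.21. Of 25 markers of apical radial glia, the stem cells at the ventricle, 20 were above 0, with a median of 0.16. Among 21 genes of the cyclin D, CDK and RB machinery, 16 were above 0 and the median was 0.10. The adjusted p of the list test (limma cameraPR, 31 lists) was 6.2e-10 for G1/S, 4.6e-09 for G2/M, 1.3e-09 for intermediate progenitors, 1.0e-06 for radial glia and 0.0032 for the cyclin D list. Few single members were called. Over all genes, 0 of 35 G1/S, 0 of 30 G2/M, 0 of 17 intermediate progenitor and 0 of 21 cyclin D genes were called by DESeq2, and 1 of 25 radial glia genes, Lhx2, was. Adjusted over the list alone, 0 G1/S, 0 G2/M and 0 cyclin D genes, 3 intermediate progenitor markers and 2 radial glia markers passed, all higher. At an unadjusted p under 0.05 there were 5 G1/S, 0 G2/M, 6 intermediate progenitor, 7 radial glia and 0 cyclin D genes. For comparison, 858 of all 14638 tested genes had an unadjusted DESeq2 p under 0.05, against 732 expected by chance, and 48.0% lay above 0.

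Examples with the smallest p in each list show the sizes in the authors' deposited table. The replication helicase subunits Mcm7 and Mcm2 stood at 0.26 (SE 0.12) and 0.27 (SE 0.13) in the authors' deposited table. There, the uracil glycosylase Ung stood at 0.29 (SE 0.13) and the chromatin remodeler Hells at 0.35 (SE 0.16). Top2a, the topoisomerase of dividing cells, stood at 0.27 (SE 0.14) and the mitotic kinesin Kif11 at 0.26 (SE 0.14) in the authors' deposited table. Neurog1, a proneural transcription factor, stood at 0.61 (SE 0.19, adjusted p = 0.18) in the authors' deposited table. That deposited table had Rhbdl3 at 0.32 (SE 0.10), Insm1 at 0.21 (SE 0.08) and Neurog2 at 0.24 (SE 0.10). Among radial glia markers other than Lhx2, Aldoc was at 0.29 (SE 0.10), Sox9 at 0.39 (SE 0.14) and Mfge8 at 0.27 (SE 0.11) in the authors' deposited table. The cyclin D list held Cdkn2c at 0.26 (SE 0.14), E2f3 at 0.26 (SE 0.14), Rbl1 at 0.27 (SE 0.15) and E2f5 at 0.22 (SE 0.13) in that deposited table. The test set the correlation among members at 0.01. At 0.3 the adjusted p was 0.147 for both cell cycle lists, 0.167 for radial glia and 0.043 for intermediate progenitors. For the cyclin D list it was 0.090 at a correlation of 0.1. In the same comparison, microglial, endothelial and rostral cortical lists were lower and the caudal cortical list higher, with the values given for those lists. Rn45s, a ribosomal RNA gene, and Lars2, which can collect ribosomal RNA reads, stood at -0.20 (SE 0.06, unadjusted p = 0.00127, adjusted p = 0.187) and -0.27 (SE 0.09, unadjusted p = 0.00219, adjusted p = 0.249) in the authors' deposited table.

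Neuronal maturation genes moved the other way. Of 23 such genes, 18 were below 0, with a median log2 fold change of -0.09 (list test, adjusted p = 0.00018). Of these genes, 0 of 23 were called over all genes by DESeq2, 5 fell adjusted over the list alone, and 6 had an unadjusted p under 0.05, 5 lower and 1 higher. Syt1, a calcium sensor of synaptic vesicles, was at -0.33 (SE 0.09, adjusted p = 0.12) in the authors' deposited table. There, the growth-cone protein Gap43 and the tubulin regulators Stmn2 and Stmn3 were at -0.27 (SE 0.08), -0.28 (SE 0.09) and -0.24 (SE 0.08). Markers of deep-layer neurons showed no shift as a list, with 8 of 14 above 0, a median of 0.04 and an adjusted p of 0.526. None of these 14 genes was called over all genes and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05. In the authors' deposited table these were Ldb2 at -0.27 (SE 0.12), Sox5 at 0.16 (SE 0.08) and Tle4 at 0.20 (SE 0.10). Upper-layer markers split, with 7 of 14 above 0, a median of -0.01 and an adjusted p of 0.361. Both Rorb, which fell, and Tcf4, which rose, belong to this list. Adjusted over the list alone, Plxna4, at -0.24 (SE 0.07) in the authors' deposited table, joined them, which gave 2 falls and 1 rise. At a correlation of 0.3 among members, the adjusted p of the maturation list was 0.270.

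Genes that mark position along the cortex differed as well. Genes with higher expression in caudal cortical progenitors rose as a list, with 8 of 10 above 0 and a median of 0.30 (adjusted p = 7.9e-07). Genes of the rostral, FGF-driven programme fell as a list, with 10 of 11 below 0 and a median of -0.24 (adjusted p = 0.0018). In the caudal list 1 gene, Lhx2, was called over all genes and 4 rose adjusted over the list alone. Besides Lhx2 these were, in the authors' deposited table, Fgfr3 at 0.47 (SE 0.14), Dmrt3 at 0.90 (SE 0.29) and Emx1 at 0.32 (SE 0.10). Among the members that did not pass were Nr2f1 at 0.27 (SE 0.29), Nr2f2 at -0.29 (SE 0.67) and Dmrta1 at -0.20 (SE 0.23) there. In the rostral list 0 genes were called over all genes and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05. Fgf15 stood at -1.35 (SE 0.50), Etv1 at -0.38 (SE 0.17) and Spry4 at -0.68 (SE 0.37) in the authors' deposited table. Markers of choroid plexus and cortical hem, tissues at the medial edge of the cortex, rose as a list, with 10 of 12 above 0 and a median of 1.56 (adjusted p = 9.8e-05, 0 called over all genes, 4 adjusted over the list alone, 4 at an unadjusted p under 0.05). Their values in the authors' deposited table were wide, with Ttr, the main transcript of choroid plexus, at 5.30 (SE 2.17), Folr1 at 4.45 (SE 1.58), Clic6 at 2.64 (SE 1.09) and Lmx1a at 1.81 (SE 0.74). All 30 reads of Wnt3a, a signal of the hem, came from 1 edited library. Kcne2 and Wnt8b had SEs of 3.63 and 3.66 in the authors' deposited table, close to the 3.76 of Prr32, which was read in 1 edited library only. How many edited brains carry the rise of this list is therefore not known. With a mean of at least 100 normalized counts the list kept 3 genes, too few for the list test. At a correlation of 0.3 the adjusted p was 0.043 for the caudal, 0.242 for the rostral and 0.167 for the choroid plexus and hem list.

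Markers of several cell types from outside the cortical neuroepithelium were lower in the edited brains. All 18 markers of microglia and macrophages were below 0, with a median of -0.59 (adjusted p = 3.4e-10), 0 called over all genes, 4 that fell adjusted over the list alone and 8 at an unadjusted p under 0.05. In the authors' deposited table the complement genes C1qb, C1qa and C1qc stood at -0.81 (SE 0.27), -0.64 (SE 0.24) and -0.64 (SE 0.25), and Ptprc, the leukocyte surface protein CD45, at -1.03 (SE 0.38). Endothelial markers fell as a list, with 14 of 16 below 0 and a median of -0.29 (adjusted p = 2.6e-05, 0 called over all genes, 0 adjusted over the list alone, 2 at an unadjusted p under 0.05). Among them were the tight-junction gene Cldn5 at -0.44 (SE 0.16) and Eng at -0.36 (SE 0.14) in the authors' deposited table. Markers of meninges and fibroblasts fell as a list, with 15 of 18 below 0 and a median of -0.80 (adjusted p = 0.0049, 0 called over all genes, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05). Examples were Foxc2 at -2.90 (SE 1.03) and Ptgds at -1.01 (SE 0.55) in the authors' deposited table. Oligodendrocyte precursor markers fell as a list, with 4 of 5 below 0 and a median of -0.29 (adjusted p = 0.026, 0 called over all genes, 1 that fell adjusted over the list alone, 2 at an unadjusted p under 0.05). That gene was Sox10, at -1.67 (SE 0.47) in the authors' deposited table. The other members stood there at -0.99 (SE 0.49) for Pdgfra, -0.29 (SE 0.36) for Olig1, -0.08 (SE 0.21) for Cspg4 and 0.41 (SE 0.84) for Olig2. The fall of this list thus rested mainly on Sox10 and Pdgfra, and a loss of the cells themselves was not shown. Pericyte markers (7 of 9 below 0, median -0.14, adjusted p = 0.066), Cajal-Retzius cell markers (10 of 11 below 0, median -0.20, adjusted p = 0.117) and erythroid markers (5 of 7 below 0, median -0.12, adjusted p = 0.356) did not pass. Of their genes, 0 were called over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Pericyte markers, with a median of -0.23, passed the list test under both other filters on low counts. The adjusted p was 0.047 with no filter and 0.039 at a mean of at least 100 normalized counts. Markers of GABAergic interneurons did not pass either (11 of 18 above 0, median 0.02, mean Wald statistic -0.42, adjusted p = 0.260). They held 1 call over all genes and 1 adjusted over the list alone, the neuropeptide gene Npy, which fell by 0.76 (SE 0.19) in the authors' deposited table. Markers of the ganglionic eminence and striatum (8 of 16 above 0, median -0.03, adjusted p = 0.601) had 0 calls over all genes, 1 gene at an unadjusted p under 0.05 and 1 fall adjusted over the list alone, both Penk at -1.26 (SE 0.33) in the authors' deposited table. Both lists held members with wide errors there, such as Dlx2 at 0.41 (SE 0.77) and Isl1 at 0.39 (SE 1.55). Other members had smaller errors, such as Lhx6 at 0.02 (SE 0.14) and Drd1 at -0.11 (SE 0.16). A list median near 0 therefore does not show equal levels in each brain. Only 4 diencephalon markers could be tested, too few for the list test, 2 above and 2 below 0, with 0 called over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. A library pair from litter 2 or 3, called pair B, stood apart. The search, which can miss genes, found 13 genes read in its control library alone, among them Prss56 with 470 reads, and 12 in its edited library alone. At a correlation of 0.1 the adjusted p was 0.081 for oligodendrocyte precursors and 0.090 for meninges, and at 0.3 it was 0.167 for endothelium and 0.043 for microglia.

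**Figure D3:**
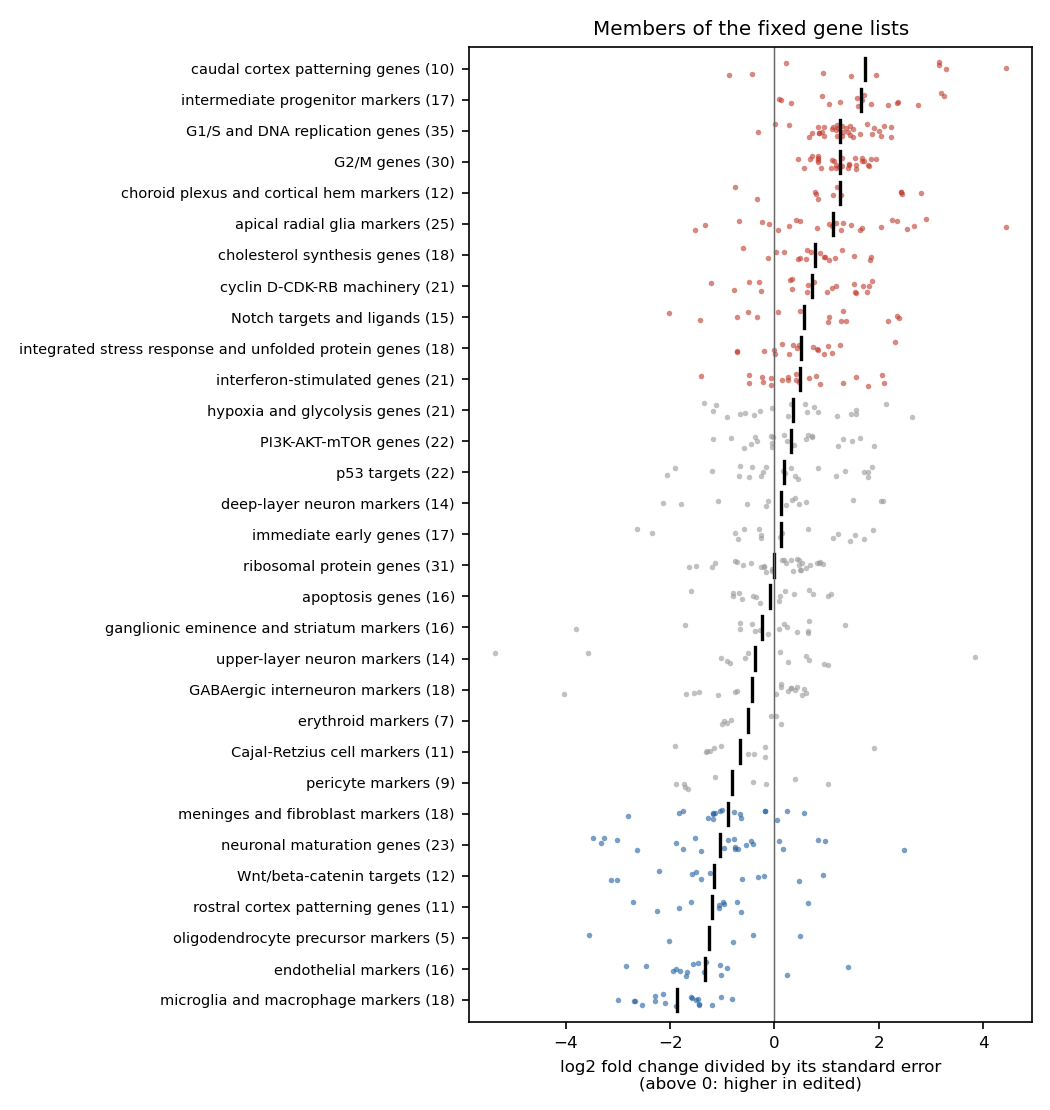
Log2 fold change divided by its SE (x axis, above 0 means higher in the edited brains) for each tested gene of the 31 tested lists (y axis, number of tested genes in parentheses). Black bars are list means, and lists with an adjusted p below 0.05 are red (11 higher) or blue (7 lower).

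Of the signalling and stress lists, 5 passed the list test. Targets of Wnt and beta-catenin signalling fell as a list, with 10 of 12 below 0 and a median of -0.36 (adjusted p = 0.0018), 0 called over all genes, 3 at an unadjusted p under 0.05 and 2 that fell adjusted over the list alone. These were the secreted ligand gene Bmp4 at -3.10 (SE 0.99) and the Wnt antagonist gene Apcdd1 at -0.31 (SE 0.10) in the authors' deposited table. Bmp4 had a mean of only 29.0 normalized counts. Axin2 at -0.04 (SE 0.20), Znrf3 at -0.06 (SE 0.19) and Lef1 at 0.15 (SE 0.33) lay near 0 in that deposited table. The 7 list genes with a mean of at least 100 normalized counts still passed the list test (adjusted p = 0.011). Pathway activity itself was not measured. Cholesterol synthesis genes rose as a list, with 16 of 18 above 0 and a median of 0.06 (adjusted p = 0.0032), such as Cyp51 at 0.13 (SE 0.07) and Idi1 at 0.19 (SE 0.10) in the authors' deposited table. Notch targets and ligands (10 of 15 above 0, median 0.15, adjusted p = 0.044), interferon-stimulated genes (14 of 21 above 0, median 0.16, adjusted p = 0.044) and genes of the integrated stress and unfolded protein responses (14 of 18 above 0, median 0.05, adjusted p = 0.047) passed narrowly. Examples in the authors' deposited table were Hey1 at 0.32 (SE 0.13), Isg15 at 1.12 (SE 0.54) and Psat1 at 0.25 (SE 0.11). In these 4 rising lists 0 genes were called over all genes and 0 adjusted over the list alone, with 0 cholesterol, 4 Notch (3 higher, 1 lower), 2 interferon and 1 stress gene at an unadjusted p under 0.05. The Notch list shares Hes1, Hes5, Notch1 and Notch2 with the radial glia list and Dll1 and Dll3 with the intermediate progenitor list, all above 0. Among its other members, Hey1, Nrarp, Lfng and Notch3 lay above 0 and Hey2, Heyl, Dll4, Jag1 and Jag2 below. The Notch rise was therefore not separated from the progenitor rise. At a correlation of 0.1 the adjusted p was 0.083 for cholesterol synthesis, 0.220 for Notch and 0.249 for both interferon and stress genes, and at 0.3 it was 0.242 for Wnt targets. With only genes of at least 100 normalized counts, it was 0.110 for Notch, 0.555 for interferon (median 0.04) and 0.199 for stress genes. Against matched random lists it was 0.208 for cholesterol synthesis and 0.282 for stress genes. Genes of PI3K, AKT and mTOR signalling (12 of 22 above 0, median 0.02, adjusted p = 0.141), p53 targets (12 of 22, 0.03, 0.356), apoptosis genes (8 of 16, -0.01, 0.995), immediate early genes (9 of 17, 0.01, 0.526), hypoxia and glycolysis genes (12 of 21, 0.04, 0.119) and ribosomal protein genes (17 of 31, 0.01, 0.746) did not pass. They had 0 calls over all genes and 0 adjusted over the list alone, and 0, 1, 0, 2, 2 and 0 genes at an unadjusted p under 0.05. In the authors' deposited table their smallest p belonged to Akt2 at 0.12 (SE 0.06), Pmaip1 at -0.86 (SE 0.42), Bak1 at -0.20 (SE 0.12), Klf6 at -0.36 (SE 0.14), Ak4 at 0.43 (SE 0.17) and Rpl38 at -0.26 (SE 0.16).

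The sex of the embryos is not given in the labels, and sex-linked genes were read only as levels. In the authors' deposited table the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty stood at -2.14 (SE 1.85), -2.07 (SE 1.82), -2.05 (SE 1.85) and -1.82 (SE 1.78), and Xist at 2.70 (SE 3.46). Of these 5, 0 were called over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. With SEs this wide, the lack of calls does not show that the sexes were balanced between the groups. All 6 X-linked genes with a Y-linked partner were above 0, as described below.

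With 3 edited and 4 control brains, simulated log2 changes of 0.32, 0.58 and 1.00 in 200 of 14638 genes were called in 20.3%, 57.8% and 75.8% of cases. The list tests rest on a correlation among genes that could not be estimated from the table. Their p-values do not measure the spread of a list between embryos. Of the 18 lists called at 0.01, 11 were called at 0.1 and 3 at 0.3.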

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

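The test in this part was chosen only after the result was seen. Prss56, Foxd3 and Mrgprf had reads in a single control library, the control of pair B, at 482.6, 332.7 and 317.3 normalized counts, and none in the other 3 controls or the edited libraries. Each gap fills the whole range of the 4 controls, above Dixon's 95% critical value for 4 values, which chance passes in about 1 of 20 groups. They came from a search of 748 genes, and a gene read in 1 of 4 libraries always gives such a gap. The same library alone held at least 10 reads of each of 10 other genes, among them Pamr1, Col6a6 and Osr2 with 26, 24 and 17 reads, while the edited library of pair B alone held 12 genes, among them Prr32, Wdr63 and Dynlrb2 with 90, 49 and 22 reads.

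Foxd3, Prss56, Sox10 and Erbb3 are used by neural crest glia, which include the ensheathing glia of the olfactory nerve. Olfactory ensheathing glia in the tissue of that control library may be the source, but the table leaves this open, since 0 members of an ensheathing glia list other than Prss56 and Foxd3 themselves were found to be read in that library alone. The search can miss genes. As a difference between the groups, the 12 tested members had a median log2 fold change of -1.50, and the 8 members without Foxd3, Prss56, Sox10 and Npy one of -1.26, with 0 above 0. Sox10 stood at -1.67 (SE 0.47) and Erbb3 at -2.30 (SE 0.72) in the authors' deposited table, at means of 130 and 70.4 normalized counts, and these values do not show which library carries them. The list was written after several of these values were known and shares Sox10 with the oligodendrocyte precursor list and Npy with the interneuron list, and neither a swapped label nor a biological difference was tested.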

How the results depend on the processing

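The tests with an adjusted p below 0.1, preset correlations, ranks and matched random lists were chosen only after the result was seen. No paired analysis was possible because the table has no values per library, although litter was a term of the authors' model. For the same reason the models planned for counts per library (a quasi-likelihood fit, and DESeq2 and limma-voom in its place), other normalizations and pseudocounts, the fit with no litter, leaving out each brain or litter, the summed litter 1 controls, the estimated correlation, fry, and other splits of the samples were not run. Gene calls numbered 36 (9 higher, 27 lower), 31 with no filter, and 34 at a mean of at least 100 normalized counts, and both of these sets lay within the 36. Leaving out the 5 sex-linked genes, none of them called, tests nothing here (36 genes, 18 lists). At an adjusted p below 0.1 there were 57 genes, 45 of them lower and 12 higher. Ccnd2 did not pass under either filter. Of 21 named genes, 17 kept their call with no filter, where more genes are tested. Called lists numbered 18, against 19 with no filter, 15 at a mean of at least 100 (of 30 tested, without choroid plexus and hem), 17 by ranks, 17 against matched random lists, and 15, 11 and 3 at correlations of 0.05, 0.1 and 0.3. No called list changed direction. The 3 lists called at 0.3 were intermediate progenitors, microglia and caudal patterning. The loss with correlation follows from the construction of the test, which widens its error, and for the other changes the cause was not tested. By ranks, Notch genes (adjusted p = 0.084) and oligodendrocyte precursor markers (0.118) were lost and Cajal-Retzius markers (0.046) gained. Against matched random lists, stress genes (adjusted p = 0.282) and cholesterol synthesis (0.208) were lost and Cajal-Retzius markers (0.033) gained, and pericyte markers were gained with no filter (0.047) and at a mean of at least 100 (0.039), where Notch (0.110), interferon (0.555) and stress genes (0.199) were lost. Of simulated 2-fold changes, 93.8% were called above a mean of 100 against 75.8% at any mean, and as the SEs hold counting error and spread between embryos, the share due to depth was not tested.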

Other observations

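The gene families below and all tests in this part were chosen only after the result was seen, except the test of radial glia standard errors. Genes of 4 receptor and ion channel families, taken by symbol and not limited to neurons, were mostly below 0 in the edited brains. Of 25 glutamate receptor subunits, 19 were below 0, with a median log2 fold change of -0.23 (cameraPR, adjusted p = 5.9e-07 over 8 added lists), 1 called over all genes, Grin3a, and 2 adjusted over the list alone. In the authors' deposited table the NMDA receptor subunit Grin2b was at -0.41 (SE 0.16). Grin3a, the gene with the smallest p of all, was kept in this list, and Grin2b and Gria2 also belong to the maturation list. No test without these genes was run. Of 12 GABA-A receptor subunits, 10 were below 0, with a median of -0.27 (adjusted p = 1.1e-04), and Gabra5 stood at -0.53 (SE 0.19) in the authors' deposited table. Sodium and calcium channel subunits were below 0 in 32 of 34 cases, with a median of -0.20 (adjusted p = 3.3e-06). Potassium channel subunits were below 0 in 53 of 68 cases, with a median of -0.11 (adjusted p = 0.0040), and Kcna2 stood at -0.90 (SE 0.25, adjusted p = 0.099) in the authors' deposited table. The potassium channels, among them the glial Kcnj10 at 0.40 (SE 0.15) in the authors' deposited table, did not pass against matched random lists (unadjusted p = 0.0621) or at a correlation of 0.1 among members (adjusted p = 0.173), while the other 3 families passed both. At a correlation of 0.3, the adjusted p was 0.070 for both receptor families, 0.125 for sodium and calcium channels and 0.410 for potassium channels.

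Cilium, olfactory bulb and X-linked genes also differed as families. Motile cilium genes were above 0 in 15 of 18 cases, with a median of 0.36 (adjusted p = 0.0067, and 0.085 at a correlation of 0.1), with Cfap126 at 2.49 (SE 0.92) and Foxj1, their master regulator, at 0.61 (SE 0.27) in the authors' deposited table. The edited library of pair B alone held reads of Wdr63, Dynlrb2, Ttc29 and Nme9, cilium genes outside this list, with 49, 22, 11 and 11 reads. Which libraries carry the rise of the cilium list itself is not known, and it was not separated from that of the choroid plexus list. Of 6 olfactory bulb projection neuron markers, 5 were below 0, with a median of -1.50 (adjusted p = 0.0017, and 0.070 at a correlation of 0.3), and Cdhr1 and Nts stood at -5.32 (SE 1.41) and -3.84 (SE 1.26) in the authors' deposited table. All 6 X-linked genes with a Y-linked partner were above 0, with a median of 0.19 (adjusted p = 5.9e-07), 0 called over all genes and 4 adjusted over the list alone, among them Kdm6a at 0.40 (SE 0.14) and Eif2s3x at 0.40 (SE 0.11) in the authors' deposited table. Ddx3y and the other Y-linked genes lay below 0 and Xist above 0, each within 2 SE of 0, and the 4 called genes on chromosome X were not separated from a difference in sex between the groups. Gene span and log2 fold change had a Spearman rho of 0.0112 across 14579 genes, which are not independent replicates.

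Progenitor and cell cycle lists were higher and the neuronal maturation list lower. A lower share of immune and vascular cells, whose markers fell, would raise progenitor and neuronal genes alike, but the mean of the radial glia and intermediate progenitor medians lay 0.2717 (bootstrap interval over genes 0.199 to 0.351) above the neuronal median. As measured, these medians did not rise alike. The interval treats genes as independent and does not cover the spread between embryos, and the difference is the pattern that prompted the test. Whether this share is the whole cause is therefore not settled. Tissue from a more caudal and medial, less mature position in the edited brains may account for the pattern, since the caudal list lay 0.5373 above the rostral list, and 0.518 (bootstrap interval over genes 0.0833 to 0.738) without Lhx2 and Emx2, which it shares with the radial glia list, with the choroid plexus and hem list up. The caudal genes Nr2f1, Nr2f2 and Dmrta1 did not pass. How many edited brains carry the choroid plexus and hem rise is not known. The Wnt target list went down (10 of 12 below 0, median -0.36), although Wnt3a is a signal of the hem. Olfactory bulb projection neuron markers were also lower (5 of 6 below 0, median -1.50). How the Wnt and olfactory bulb lists bear on position was not tested. As the caudal list holds genes of progenitors, its rise was not separated from the progenitor rise. The Ccnd2 edit itself, which the design names, stays open and cannot be told apart from position, because 0 samples in the table were matched for position. A difference in developmental stage between embryos of a litter was not tested.

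The SE of Ccnd2 was 3.65 times that of genes of like abundance, and of 347 genes with a mean of at least 10000 normalized counts none had a higher ratio, the next being Nfib at 1.90, while 1.34% of the 11356 genes with a mean of at least 100 did. A disturbance of the surrounding region of chromosome 6 that affects neighbouring genes as much as Ccnd2 is argued against by their SEs. The 13 tested genes within 1000000 bases had a median ratio of 1.039 (bootstrap interval 0.903 to 1.09). These genes cannot decide on a change limited to Ccnd2. Nor can they decide on one that they show less because only part of the cells carry the edit. A progenitor share that varies between brains is argued against as the whole cause by 25 radial glia markers, whose median ratio was 1.394 (bootstrap interval 1.24 to 1.68), below the 2 it was set to need, although Sox2 and Lrig1 had ratios of 3.96 and 3.99. A change of Ccnd2 transcripts in part of the edited brains may account for it and cannot be told apart from a difference among controls, since 0 values of Ccnd2 per brain are in the table. Some interneuron markers also had wide errors in the authors' deposited table, such as Dlx2 (SE 0.77) and Gad2 (SE 0.65). Others, such as Lhx6 (SE 0.14) and Erbb4 (SE 0.16), did not. A share of ganglionic eminence cells or interneurons that varies between brains was not tested as a source. DESeq2 by default leaves the dispersion of genes far above its trend unshrunken, which sets such genes apart from the rest in the plot of standard errors, and how much of the ratio this adds was not tested.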
